A study of Rattus norvegicus with 8 samples.

How the data were processed

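RNA of the tibialis anterior of 8 rats was hybridised to Affymetrix expression arrays, 1 array per rat as the labels describe them, with 4 hyperthyroid and 4 control rats. Replicates 1, 3, 5 and 2 were hyperthyroid and replicates 7, 8, 9 and 11 were controls. The groups share no replicate number, so no pairing was fitted. The labels give rats of 200 ± 40 g at the start and do not say which array is the female of each group. The design text names RNA of EOMs from the same animals, for which this limb muscle served as the reference, and those samples were not analysed here. Complementary RNA was made from oligo(dT)-primed cDNA and labelled with biotin, per the labels' protocols, so signal depends on sequence near the 3' end of a transcript.

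The deposited values are intensities on a linear scale, and GCOS, the Affymetrix software, is named in the submitters' processing notes. Its version and settings are not given in the sources used here. On every array the mean of the values was 150 after 2% were left out at each end, which is the mark of scaling each array to 1 target. Such scaling removes any difference in total RNA between arrays and leaves a difference in the shape of the distribution. Background correction, the summary of probes and detection calls were not examined, and no scanner values were used here.

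Of 31099 probe sets, 57 were controls, 20826 carried 1 gene symbol, 436 several and 9780 none in the platform annotation. Entrez identifiers matched 20758 of the 20826 to RefSeq genes (assembly GRCr8), which was used for names only, and no symbol changed. No genome build is given for the arrays, so no coordinates are printed. Probe sets with several symbols or none were tested but not named.

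Values were analysed as log2(intensity + 3.41), the pseudocount being the 10th percentile of all values. Fold changes are on that scale and understate the change of low transcripts. Probe sets were kept when their mean log2 value over all arrays lay above the 40th percentile, 4.69, or an intensity of about 22.4. This left 18625 probe sets. No further normalization was made. Each probe set was tested with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with a trend of variance on level, two-sided, and Benjamini-Hochberg adjustment at 0.05. At gene level, 10200 genes were each represented by the kept probe set with the highest mean. The prior had 6.88 degrees of freedom. Standard errors are those of limma.

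Gene lists for fibre type, T3 response, metabolism, growth, stress, matrix and cell types were fixed before the data were examined. The 31 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists. Camera with an estimated correlation and fry were alternatives. All other alternatives, among them those with arrays left out, kept the preset correlation. Estimated correlations of the 6 lists called at the preset ran from 0.128 to 0.676. With an estimated correlation no list was called, no list had an unadjusted p under 0.05, and the smallest adjusted p was 0.669. Fry called no list in 1 direction (3 with an unadjusted p under 0.05) and 6 lists in either direction, of which only the fast-fibre list was also called by camera. The other 5 were the developmental, mitochondrial biogenesis, glycolysis, glycogen and cytosolic ribosomal lists (adjusted p = 0.000377, 0.0425, 0.0157, 0.00562 and 9.08e-05). Members are counted past 0.05 over all genes and adjusted over the list alone. The mean log2 level of a list and 6 technical measures were compared with exact permutation tests over the 70 assignments of 4 and 4 arrays, whose smallest p is 0.0286. For the lists these p-values were not adjusted, and 3 of the 31 lists reached that smallest value. Several lists share genes, such as Thrsp in those of T3 response and adipocytes and Igfbp5 in those of atrophy and growth factors. Erythroid markers had fewer than 5 measured genes and were not tested, and sex-linked genes served only to check the arrays.

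The rule for named genes was also fixed before the data were examined. It took up to 12 rises and 12 falls among genes past 0.05 whose groups did not overlap, up to 4 members of each list with the smallest p, and 17 genes whatever their values. All 7 genes of the first part and all 17 of the last are reported, and of the list members a part is named and the rest is counted. Apart from the sex-linked genes, genes named outside the rule are said to have been chosen after their values were seen.

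Alternatives were quantile normalization, centring on array medians, a floor of 1.12 in place of the pseudocount, a pseudocount of 12.6 at the 25th percentile, no filter, a filter at the 60th percentile, no variance trend, a robust variance, array weights, the mean of all probe sets of a gene, a 2-fold minimum, an adjusted p under 0.01, and each array left out. Chosen after seeing the data were scaling to 18 hybridization control probe sets, the level of Xist as a covariate, and the removal of both arrays with high Xist or of control replicates 7 and 11. The steps were tested on simulated arrays with the observed means and spread, in which 200 of 18625 probe sets were changed. Of 50 changed by log2 1, 26% were recovered, with 46% at log2 1.5, 74% at log2 2 and 72% at log2 3, and 3 unchanged probe sets were called. With no change simulated, 0 probe sets and 0 lists were called. These simulated genes vary independently, so the list result of that test does not cover correlated genes. Tables and figures were made with the R package data.table (version 1.17.8), pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 in python 3.11.15.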

Results

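Gene expression was measured in the tibialis anterior, a fast-twitch muscle of the hind limb, of 8 Sprague-Dawley rats. In the hyperthyroid group, 4 rats had received triiodothyronine (T3, the active thyroid hormone) by intraperitoneal injection at 25 µg per 100 g of body weight every 2 days for 6 weeks. They were killed 24 hours after the last dose. The other 4 rats were untreated controls. Each group held 3 males and 1 female. The comparison asked which transcripts of this limb muscle differ after prolonged T3 excess. Each array gave 31099 intensities with a mean of 150 after the highest and lowest 2% were left out, and array medians ran from 38.8 to 54.9. With 4 arrays per group, the number of arrays limits the precision of every value below.

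Of the 10200 genes tested, 7 were higher in the hyperthyroid group, and no gene passed the threshold in the other direction. Gpcpd1, a phosphodiesterase that breaks down glycerophosphocholine, rose 3.42-fold, from an intensity of 566 ± 174 in controls to 1884 ± 158 (SD, n = 4 each, limma adjusted p = 0.00504). Agpat3, an acyltransferase that makes phosphatidic acid, rose 3.82-fold, from 90.2 ± 25.9 to 366 ± 162 (SD, n = 4 each, limma adjusted p = 0.0387). Mcl1, an anti-apoptotic member of the BCL2 family, rose 2.17-fold from 835 ± 137 to 1805 ± 190 (SD, n = 4 each, limma adjusted p = 0.014). Pcyox1, which degrades prenylated cysteines, rose 2.44-fold, and Mrps18c, a protein of the mitochondrial ribosome, rose 2.17-fold. Ppp1r2, a regulatory inhibitor of protein phosphatase 1, rose 1.95-fold.

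The log2 fold changes with their standard errors were 1.77 ± 0.19 for Gpcpd1, 1.93 ± 0.29 for Agpat3 and 1.12 ± 0.15 for Mcl1. They were 1.29 ± 0.20 for Pcyox1, 1.12 ± 0.18 for Mrps18c and 0.96 ± 0.15 for Ppp1r2, the last 3 with a limma adjusted p of 0.0387 each. Syncrip-ps2, annotated as a pseudogene of the RNA-binding protein gene Syncrip, rose by 1.23 ± 0.15 (limma adjusted p = 0.0109). The probe set of Syncrip itself, a gene chosen after its value was seen, differed by -0.18 ± 0.16 (limma adjusted p = 0.7196), and whether the pseudogene's probe set detects other Syncrip-like transcripts was not tested. All 4 hyperthyroid arrays lay above all 4 control arrays for each of these 7 genes. Other probe sets did not always move alike: of those that passed the filter, for Mrps18c another gave -0.19 ± 0.22, and for Ppp1r2 they gave 0.18 ± 0.21 and 0.11 ± 0.23. The second probe sets of Gpcpd1 and Mcl1 gave 0.88 ± 0.34 and 0.37 ± 0.23, while those of Agpat3 gave 2.22 ± 0.65 and 1.30 ± 0.81. Under the filter, on low values, 3 probe sets of Agpat3 gave -1.17 ± 0.75, -1.42 ± 0.74 and -1.05 ± 0.83, and 1 of Mrps18c gave -1.34 ± 0.59.

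**Figure D1:**
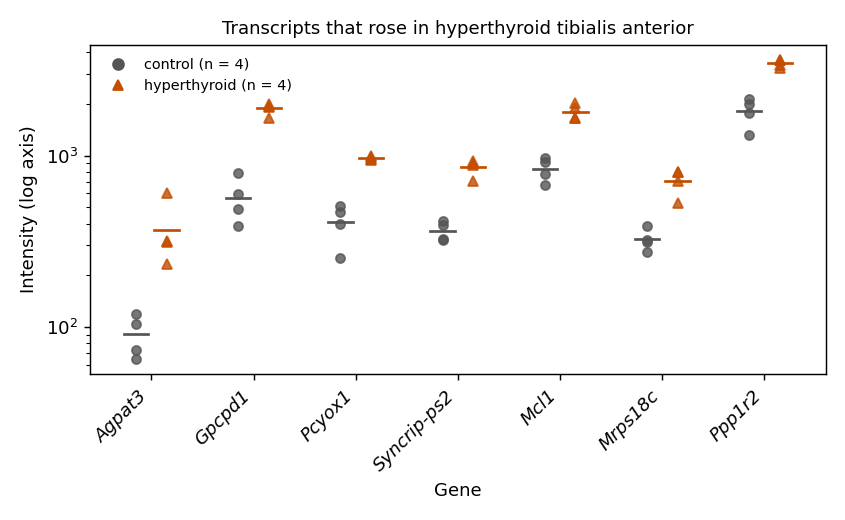
Intensity (log axis) of the 7 transcripts that rose, with a grey circle per control array, an orange triangle per hyperthyroid array (n = 4 each) and a bar at each group mean. In each gene the 4 hyperthyroid arrays lie above the 4 control arrays, with the mean of Gpcpd1 at 1884 against 566.

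At the level of single probe sets, 6 of 18625 passed, all of them higher in the hyperthyroid group. These were the probe sets of Gpcpd1, Syncrip-ps2, Mcl1, Pcyox1 and Agpat3, and a probe set that carries no gene name here (log2 fold change 1.36 ± 0.19). An unadjusted p under 0.05 was reached by 1080 genes against 510 by chance, 549 of them higher and 531 lower. The arrays of both groups did not overlap for 668 genes (6.55%, with 2.86% by chance). No gene passed without hyperthyroid replicate 3 or without the trend of variance on level, and 1, 3 and 4 genes passed without control replicate 7, control replicate 9 and hyperthyroid replicate 2. When all probe sets of a gene were averaged, 1 gene passed. Over all kept probe sets, control replicate 11 stood apart on the first principal component (94.7, the others -25.3 to 23.9) and control replicate 9 on the second (-87.1, the others -8.96 to 26.8).

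Transcripts of slow fibres were lower in the hyperthyroid group. Of the slow-fibre contractile and calcium-handling genes, all 14 measured had a log2 fold change below 0, with a median of -1.88 (camera adjusted p = 4.94e-08). The list was not called with an estimated correlation (adjusted p = 0.669). With 1 array left out the median fell to -0.96 without hyperthyroid replicate 5 and to -1.20 without control replicate 7, and the call held. Myh7, the slow myosin heavy chain, had a mean intensity of 56.6 ± 77.3 against 2120 ± 2603 in controls (SD, n = 4 each), a log2 fold change of -4.41 ± 1.29. The slow troponins Tnnc1, Tnni1 and Tnnt1 had log2 fold changes of -3.27 ± 0.97, -2.72 ± 0.85 and -4.07 ± 1.36, and Atp2a2, the slow-fibre calcium pump, had -1.75 ± 0.60. None of the 14 passed over all genes, and these 5 passed when adjusted over the list alone. Of the 3 other kept probe sets of Atp2a2, 2 were below 0, and the median of the 3 was -0.22. The other kept probe set of Myh7 gave -1.62, and that of Tnni1 gave -3.57.

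The control arrays were far apart in these transcripts. Myh7 reached 5570 and 2692 on control replicates 7 and 11, and 56.0 and 163 on control replicates 8 and 9. The hyperthyroid arrays ran from 5.83 to 169, so that 2 control arrays lay within their range. Control replicates 7 and 11 were also the highest arrays in the means of the Schwann cell and nerve markers (1.34 and 0.91, against -0.90 and -0.67 on control replicates 8 and 9), of the smooth muscle markers and of the denervation-responsive synaptic genes. The mean log2 level of the slow-fibre list differed by -2.1 (exact permutation p = 0.143, two-sided). Its SD was 1.22 over the hyperthyroid and 1.61 over the control arrays. Without control replicates 7 and 11, an alternative chosen after seeing the data that removes the arrays with the highest slow-fibre level, the median was -0.40 (adjusted p = 0.0513). Among other heavy chains, Myh2, of fast oxidative fibres, differed by -1.39 ± 0.79, Myh1 by -0.21 ± 0.22 and Myh4, of the fastest fibres, by -0.12 ± 0.14. None of these 3 passed the test. The 4 other kept probe sets of Myh1 were all below 0, with a median of -0.55.

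**Figure D2:**
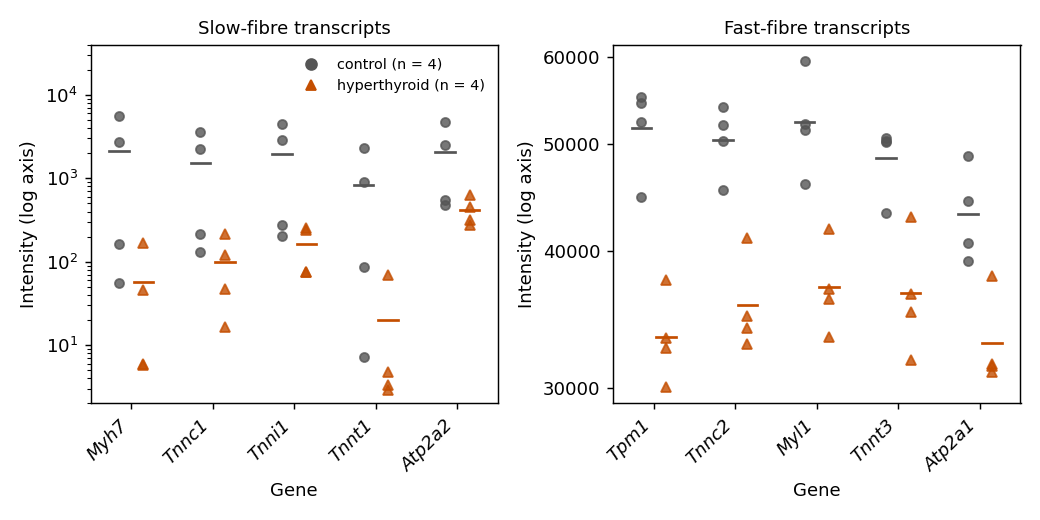
Intensity (log axes of different range) of 5 slow-fibre and 5 fast-fibre transcripts, with a grey circle per control array, an orange triangle per hyperthyroid array (n = 4 each) and a bar at each group mean. For Myh7, control arrays lie at 5570, 2692, 163 and 56.0 and hyperthyroid arrays between 5.83 and 169, whereas the groups of Tpm1 do not overlap.

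Fast-fibre contractile and calcium-handling genes were slightly lower in the hyperthyroid group, with a median log2 fold change of -0.21 over 20 genes (camera adjusted p = 0.00217). This list was not called with an estimated correlation (adjusted p = 0.669), and after quantile normalization its median was 0.10 (adjusted p = 0.364). The exact permutation p of its mean log2 level was 0.114. Tpm1, a tropomyosin, differed by -0.63 ± 0.12, Tnnc2 by -0.50 ± 0.12, Myl1 by -0.49 ± 0.13 and Tnnt3 by -0.41 ± 0.13. The other kept probe set of Tnnt3 gave 0.29. Atp2a1, the calcium pump of fast fibres, differed by -0.39 ± 0.12. None passed over all genes, and 6 of the 20 were lower when adjusted over the list alone. After quantile normalization, Myl1, Tnnt3, Atp2a1 and Myh4 had values of 0.0070, 0.073, 0.017 and 0.21, as the arrays differed in the signal of abundant transcripts. The call was also lost, with medians of -0.17, -0.19 and -0.17, without hyperthyroid replicate 1, control replicate 8 and control replicate 9 (adjusted p = 0.0534, 0.0552 and 0.0646). The call was lost as well with no filter on low values (adjusted p = 0.0914), and it held under 16 of 23 alternatives. Without hyperthyroid replicate 2 the median was -0.32 (adjusted p = 1.54e-05).

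The developmental contractile and myogenic genes were not called as a list in the main test (9 genes, median -0.11, camera adjusted p = 0.294). Adjusted over the list alone, 3 of them passed and none over all genes. Acta1, the skeletal actin, was lower by log2 -0.58 ± 0.13 and Myl4, an embryonic light chain, by -0.44 ± 0.16. Myf6, a myogenic regulatory factor, was higher by 0.71 ± 0.21. The denervation-responsive synaptic genes had a median of -0.15 (10 genes, camera adjusted p = 0.424), which turned to 0.038 without hyperthyroid replicate 3.

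Genes of T3 action were not called as a list, which holds receptors and transport genes as well as responsive genes. Of its 17 measured genes, 9 had a log2 fold change above 0 and 8 below. An unadjusted limma p under 0.05 was reached by 4 of them, all 4 higher, and by 10.6% of all genes. The list of thyroid hormone receptors, transport and responsive genes had a median log2 fold change of 0.12 over 17 genes (camera adjusted p = 0.402). The median turned to -0.060, -0.041 and -0.092 without hyperthyroid replicate 1, hyperthyroid replicate 2 and control replicate 9, and to -0.23 with no filter and -0.030 with a filter at the 60th percentile. Thrsp, a thyroid hormone-responsive regulator of lipogenesis, had an intensity of 84.4 ± 9.71 against 27.3 ± 16.2 in controls (SD, n = 4 each), and passed adjusted over the list alone but not over all genes (limma adjusted p = 0.239). This probe set had a log2 fold change of 1.68, and the 2 other kept probe sets of Thrsp, both above 0, had a median of 0.19. Hr, a corepressor whose gene T3 induces in brain, had a log2 fold change of 1.74 ± 0.62, Atp1b2, a sodium pump subunit, 0.89 ± 0.30, and Gpd2, the mitochondrial glycerophosphate dehydrogenase, 0.48 ± 0.18. The groups did not overlap for Thrsp and Hr. For Hr the margin was small, with the lowest hyperthyroid array at an intensity of 47.7 and the highest control at 46.7, and control replicate 7 was low at 6.41. The receptors themselves gave -0.43 ± 0.33 for Thra and 0.29 ± 0.21 for Thrb.

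Of the genes named whatever their values, Ucp3, an uncoupling protein, gave 0.16 ± 0.60 and Pdk4, which restrains pyruvate dehydrogenase, gave 0.10 ± 0.56. Both rested on hyperthyroid replicate 1, where Ucp3 was at 3403 and Pdk4 at 19514, and without it they were at -0.52 and -0.48. Slc2a4, the insulin-responsive glucose transporter, gave -0.18 ± 0.16, and Ppargc1a, a coactivator of mitochondrial biogenesis, gave 0.20 ± 0.24. None of the 4 passed. The other kept probe sets of Slc2a4 and Ppargc1a gave 0.012 and -0.37. Ucp2 and Dio2 lay under the filter on low values, with intensities of 8.77 ± 4.20 and 6.43 ± 5.87 in hyperthyroid and 31.6 ± 30.7 and 14.6 ± 20.9 in control muscle (SD, n = 4 each).

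Transcripts of the respiratory chain and of fatty acid oxidation were lower in the hyperthyroid group, while the list of tricarboxylic acid cycle enzymes was not called. The subunits of complexes II to V had a median log2 fold change of -0.25, with 32 of 36 genes below 0 (camera adjusted p = 2.62e-10). The complex I subunits had a median of -0.13, with 25 of 33 below 0 (camera adjusted p = 0.0131), and the fatty acid uptake and oxidation genes had -0.39, with 28 of 30 below 0 (camera adjusted p = 6.56e-08). None of these 3 lists was called with an estimated correlation (adjusted p = 0.669, 0.686 and 0.669), and the exact permutation p of their mean log2 levels was 0.114, 0.457 and 0.2. After quantile normalization the median of complexes II to V was -0.098 (adjusted p = 0.0142). Without both control replicates 7 and 11, that of the fatty acid list was -0.16 and its call was lost (adjusted p = 0.0528). This list was highest on control replicates 7 and 11 and lowest on hyperthyroid replicate 5, as the slow-fibre list was. Atp5f1e of ATP synthase differed by -0.49 ± 0.12, Sdhc and Sdhb of succinate dehydrogenase by -0.46 ± 0.12 and -0.46 ± 0.14, and Cox6a2 of cytochrome c oxidase by -0.45 ± 0.13. These 4 were among 10 genes of complexes II to V that passed adjusted over the list alone, and none passed over all genes.

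In complex I, Ndufa8, Ndufc2 and Ndufa9 differed by -0.38 ± 0.12, -0.42 ± 0.13 and -0.39 ± 0.13, whereas Ndufs4 had 0.73 ± 0.22. The other kept probe set of Ndufa9 gave 0.36. In fatty acid oxidation, Etfa and Etfb, the electron transfer flavoprotein, differed by -0.51 ± 0.14 and -0.57 ± 0.18, Hadhb by -0.37 ± 0.13 and Decr1 by -0.60 ± 0.22. No member of these last 2 lists passed adjusted over the list alone. Scaled to the hybridization controls, the medians were 0.19 for complex I and 0.072 for complexes II to V, relative to a shift of 0.32 in the median of all genes, and neither list was called (adjusted p = 0.538 and 0.0602). Complex I also lost its call after quantile normalization (median -0.060, adjusted p = 0.364) and without hyperthyroid replicate 5, control replicate 7, control replicate 8 or control replicate 11 (medians -0.033, -0.12, -0.097 and -0.11, adjusted p = 0.471, 0.0963, 0.153 and 0.0606), and held it under 12 of 23 alternatives.

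Lower values in the fast-fibre and respiratory chain lists went with lower signal among the most abundant transcripts. The 100 brightest probe sets held 22.6 ± 1.19% of the signal on hyperthyroid and 26.6 ± 0.881% on control arrays (SD, n = 4 each, exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give). Over the 125 genes with a mean log2 level of at least 13, members of these lists among them, the median log2 fold change was -0.23. It was -0.00081 after quantile normalization. That step gives all arrays the same distribution, so a median near 0 follows from it and cannot tell scaling from a real fall. Acta1 and the glycolytic enzyme Aldoa, 2 of the most abundant, differed by -0.58 ± 0.13 and -0.59 ± 0.12. Aldoa passed adjusted over the list of glycolysis enzymes alone, and that list was not called in the main test (18 genes, median -0.02, camera adjusted p = 0.257). Its mean log2 level was lower on all 4 hyperthyroid arrays than on any control array (by 0.12, exact permutation p = 0.0286), and without both control replicates 7 and 11 it was called lower (adjusted p = 0.0308). Ldhb, the lactate dehydrogenase subunit of heart and slow muscle, differed by -1.48 ± 0.57.

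The remaining lists of metabolism were not called in the main test. Medians and camera adjusted p were -0.04 and 0.293 for tricarboxylic acid cycle enzymes, 0.18 and 0.325 for glycogen metabolism, 0.04 and 0.325 for lipid synthesis, and 0.19 and 0.294 for polyamine metabolism, whose mean log2 level was higher on all 4 hyperthyroid arrays than on any control array (by 0.11, exact permutation p = 0.0286). They were -0.16 and 0.227 for amino acid and creatine metabolism, with a median of -0.070 without control replicate 7 and a call without both arrays of high Xist (median -0.20, adjusted p = 0.0324). For mitochondrial biogenesis regulators the median was 0.04 but the mean -0.04, and the camera adjusted p was 0.844. Without hyperthyroid replicate 5 the medians were 0.016 for the tricarboxylic acid cycle, -0.013 for lipid synthesis and 0.073 for glycogen metabolism. That of the tricarboxylic acid cycle was -0.10 without hyperthyroid replicate 2, and none of these was called. Ppp1r1a, an inhibitor of protein phosphatase 1 held in the glycogen list, was lower by log2 -0.47 ± 0.10, and Lpin1, a phosphatidate phosphatase, was higher by 0.70 ± 0.18. Each passed adjusted over its list alone. Gpt2, an alanine aminotransferase, gave 1.04 ± 0.28, and Ckmt2, the mitochondrial creatine kinase, gave -0.56 ± 0.17, neither of them past the threshold. The other kept probe set of Gpt2 gave -0.11.

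**Figure D3:**
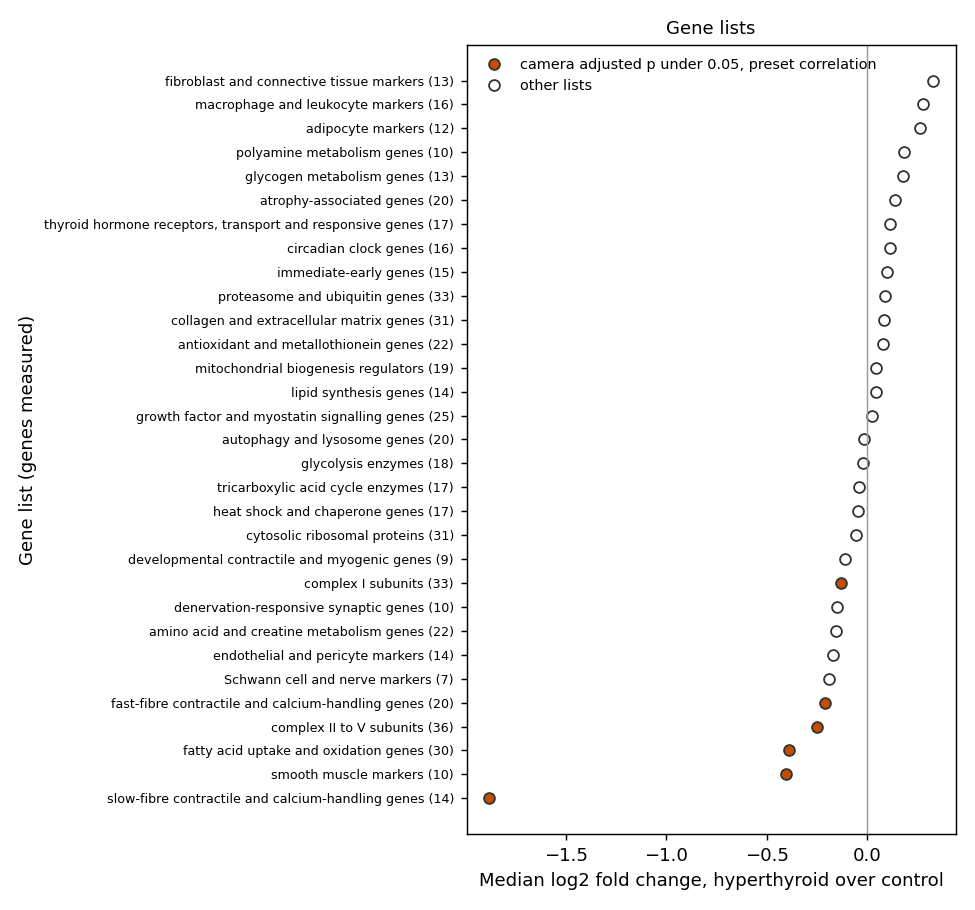
Median log2 fold change (hyperthyroid over control, 4 arrays each) of the measured members of each of the 31 gene lists, with their number in parentheses. Filled points mark the 6 lists with a camera adjusted p under 0.05 at the preset correlation, all of them below 0, and the slow-fibre list lies lowest at -1.88.

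Genes of muscle growth and protein breakdown were not called as lists in the main test. Atrophy-associated genes had a median of 0.14 over 20 genes (camera adjusted p = 0.293), with Fbxo32 and Trim63, ubiquitin ligases of muscle atrophy, at -0.13 ± 0.38 and 0.40 ± 0.29. Igfbp5, which binds insulin-like growth factors, was higher by 1.02 ± 0.21 and passed adjusted over the list alone, in this list and in that of growth factor and myostatin signalling, but not over all genes (limma adjusted p = 0.135). The latter list had a median of 0.03 (25 genes, camera adjusted p = 0.2995), and Mstn, a growth inhibitor of muscle, gave 0.93 ± 0.46. Proteasome and ubiquitin genes had a median of 0.09 (33 genes, camera adjusted p = 0.293). Without hyperthyroid replicate 2, the atrophy-associated and the proteasome and ubiquitin genes were called higher (adjusted p = 0.0281 and 0.0061), and scaled to the hybridization controls the latter were as well (adjusted p = 0.00945). For autophagy and lysosome genes the median was -0.02 and the mean 0.05 (camera adjusted p = 0.571). Among 31 cytosolic ribosomal proteins the median was -0.05 (camera adjusted p = 0.294), and Rpl34, at -0.65 ± 0.13, passed adjusted over the list alone.

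Among stress-related lists, camera adjusted p was 0.697 for antioxidant and metallothionein genes, 0.343 for heat shock and chaperone genes, 0.822 for immediate-early genes and 0.294 for circadian clock genes. Their medians were 0.08, -0.05, 0.10 and 0.12. The antioxidant median turned to -0.030 without hyperthyroid replicate 1 and -0.049 without control replicate 9. The immediate-early median turned to -0.097 and -0.014 without hyperthyroid replicates 5 and 2. It was -0.21 and -0.060 without control replicates 8 and 9. Heat shock and chaperone genes had a median of -0.15 without hyperthyroid replicate 1 and were called lower without both arrays of high Xist (median -0.25, adjusted p = 0.04), and immediate-early genes were called higher without both control replicates 7 and 11 (median 0.49, adjusted p = 0.0489). The small heat shock proteins Hspb8 and Cryab gave 0.46 ± 0.13 and -0.87 ± 0.26, neither of them past the threshold.

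Markers of smooth muscle were lower in the hyperthyroid group, as all 10 measured genes had log2 fold changes below 0 (median -0.40, camera adjusted p = 0.0061). With an estimated correlation the adjusted p was 0.669. The mean log2 level of the list was lower on all 4 hyperthyroid arrays than on any control array (exact permutation p = 0.0286, two-sided, not adjusted over the lists). Actg2, the enteric smooth muscle actin, differed by -1.44 ± 0.39 and Tagln, transgelin, by -0.79 ± 0.25, and both passed adjusted over the list alone. Smtn, smoothelin, gave -0.57 ± 0.24. Without control replicate 7 the list's median was -0.37 (adjusted p = 0.0963), without both control replicates 7 and 11 it was -0.22 (adjusted p = 0.235), and without hyperthyroid replicate 2 it was -0.62 (adjusted p = 0.00137).

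Markers of the other cell types of a muscle were not called in the main test. Medians and camera adjusted p were 0.33 and 0.293 for fibroblast and connective tissue markers, 0.27 and 0.293 for adipocyte markers, 0.28 and 0.257 for macrophage and leukocyte markers, and -0.17 and 0.293 for endothelial and pericyte markers. They were -0.19 and 0.293 for Schwann cell and nerve markers and 0.08 and 0.822 for collagen and extracellular matrix genes. Pparg, a nuclear receptor of fat cells, gave 1.56 ± 0.67, the monocyte receptor Cd14 gave 1.71 ± 0.71, the class II antigen RT1-Da gave 1.25 ± 0.54, and Rgs5 of pericytes gave -0.78 ± 0.22. Prx, of myelin, gave -1.67 ± 0.61. None of these 5 passed. Without control replicate 11, collagen and extracellular matrix genes, fibroblast markers and macrophage markers were higher in the hyperthyroid group (adjusted p = 0.00121, 0.019 and 0.00227). The preset correlation of 0.01 gave these calls, while the correlations estimated on all arrays were 0.573, 0.494 and 0.423. With those, camera on all arrays gave adjusted p = 0.943, 0.701 and 0.686. The runs without an array were not repeated with them. Without hyperthyroid replicate 2, fibroblast and macrophage markers were higher (adjusted p = 0.00764 and 0.00153). With array weights the macrophage markers were higher too (median 0.43, adjusted p = 0.0317). The macrophage median was 0.099 without hyperthyroid replicate 5 and 0.098 without control replicate 9, not called in either. The adipocyte median was -0.12 with a filter at the 60th percentile. The medians of collagen and fibroblast genes turned to -0.18 and -0.076 without hyperthyroid replicate 5, and were -0.19 and 0.043 without control replicate 8, none of them called. The direction of the collagen and fibroblast lists changed with the array left out, and so did that of the Schwann cell and nerve markers, at 0.19 without control replicate 7 and -0.72 without control replicate 8 (adjusted p = 0.904 and 0.0552).

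Technical measures differed between the groups. Median intensity was 40.5 ± 1.48 on hyperthyroid and 47.8 ± 4.89 on control arrays, and the log2 ratio of the 3' to the 5' Gapdh control probe sets was 0.339 ± 0.0533 against 0.482 ± 0.0576 (SD, n = 4 each, exact permutation p = 0.0286 each, two-sided). The beta-actin ratio was 0.723 ± 0.171 against 0.868 ± 0.228 (exact permutation p = 0.4). Hybridization controls had a mean log2 level of 11.2 ± 0.214 against 11.6 ± 0.0877, and 10.8 ± 0.697% against 9.19 ± 1.28% of values lay under the pseudocount (exact permutation p = 0.0571 each). Adjusted over the 6 measures, these exact permutation p-values ran from 0.0571 to 0.4. Without hyperthyroid replicate 2, the hybridization controls differed by -0.42 (exact permutation p = 0.0286).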

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

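The tests of the dissected piece and of abundant transcripts were chosen only after the result was seen. The other tests were written down before their values were computed, but after the calls and the levels of the fibre genes on each array had been seen. For 224 sets of 4 arrays (each named gene, gene list mean and technical measure in each group), the highest or lowest array was compared with the rest, and 16 stood apart where chance gives about 11.

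Hyperthyroid replicate 2 stood above the other 3 hyperthyroid arrays in Atp2a1 (log2 level 15.21 against 14.92 to 14.95), in Acta1 (15.55 against 15.25 to 15.29) and in the mean of its hybridization controls (11.55 against 11.1 to 11.15). It was lowest in the mean of the proteasome and ubiquitin genes, at -0.15 against 0.08 to 0.10. Control replicate 7 was the lowest control in Mstn (5.65 against 7.5 to 7.67), Tnnt3 (15.4 against 15.61 to 15.63), Hr (3.30 against 5.65 on each of the others) and Atp1b2 (8.42 against 9.74 to 10.01). Hyperthyroid replicate 1 was highest in Tnnt1 (6.18 against 2.66 to 3.03) and in the means of the autophagy and lysosome genes (0.18 against -0.04 to -0.02) and of the antioxidant and metallothionein genes (0.29 against -0.05 to -0.01). Hyperthyroid replicate 5 was lowest in Ndufc2 (12.49 against 12.62 to 12.64) and in the mean of the subunits of complexes II to V (-0.39 against -0.06 to -0.02). Control replicate 9 was lowest in the mean of the complex I subunits, at -0.18 against 0.11 to 0.14. Eif2s3y, a Y-linked gene, was low on hyperthyroid replicate 1 (2.05 against 9.02 to 9.33) and on control replicate 11 (4.52 against 8.49 to 9.26), 1 array per group. Uty, also Y-linked, did not follow: the brighter of its 2 probe sets was highest of all arrays on hyperthyroid replicate 1, at an intensity of 220.6, and at 73.1 on control replicate 11.

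The 7 genes that rose, and the 6 probe sets, were more than any other assignment of the arrays gave. Of the 35 splits of the 8 arrays into 4 and 4, only the real one reached 7 genes or 6 probe sets. The highest of the other splits gave 1 gene and 1 probe set. A share of 1 of 35 is the smallest that this test can give, so it argues against chance but cannot exclude it. A shift shared by probe sets of similar level was argued against, as the kept probe sets nearest in mean level had a median log2 fold change of 0.037. Every array was already scaled to 1 target, so this cannot test a difference in total signal. Scaled to the hybridization controls, 114 genes passed, these 7 among them. Whether each transcript or only its brightest probe set rose stays open. Pcyox1 and Syncrip-ps2 had no other kept probe set, so this was not assessed for them. The 7 other kept probe sets of the remaining genes had a median of 0.37. This lies between the value a change of the transcript and that of a lone probe set would give. By gene they were 2.22 and 1.30 for Agpat3, 0.88 for Gpcpd1 and 0.37 for Mcl1. For Ppp1r2 they were 0.18 and 0.11, and for Mrps18c -0.19. An effect of T3 on these genes, the biological explanation that the design offers, therefore remains a hypothesis, and technical measures also differed between the groups, while the labels do not give the batches in which the arrays were hybridised.

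The slow-fibre list, with Myh7, Tnnc1, Tnni1, Tnnt1 and Atp2a2, was lower on the hyperthyroid arrays by a mean of 2.10 on the log2 scale, and its 2 highest arrays, control replicates 7 and 11, were also highest in the Schwann cell and nerve markers and in the smooth muscle markers. Signal scaling was argued against, as the list's median was -1.91 after quantile normalization. Chance cannot be excluded, since 5 of the 35 splits gave a difference as large and the highest other split gave 2.23. A candidate explanation is that the dissected pieces differed in slow-fibre content whatever the treatment: 2 of the 4 control arrays lay within the range of the hyperthyroid arrays, and the controls spread over 3.18, more than the difference between the groups. A loss of slow-fibre transcripts under T3 stays open as the biological explanation that the design gives.

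The fast-fibre list, with Tpm1, Tnnc2 and Myl1, was lower on the hyperthyroid arrays by a mean of 0.21. Chance cannot be excluded, as 4 of the 35 splits gave a difference as large and the highest other split gave 0.29. The shift may be part of a lower signal of abundant transcripts. The 119 genes nearest in mean level outside the fast- and slow-fibre lists had a median log2 fold change of -0.11, against -0.21 for the list. They were matched by level only and may include other muscle genes. Only 43 genes in all had a mean log2 level of at least 14, so the brightest members lack close matches. The comparison therefore cannot tell a general signal effect from a fall of muscle transcripts. Differences in signal scaling between arrays also stay possible. The list's camera p was 0.111 after quantile normalization, but that step would also remove a real fall of the brightest transcripts. It therefore cannot tell scaling from biology here. A fall of these transcripts under T3 was not tested apart from these explanations.

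The 6 lists called with camera's preset correlation were not more than other splits gave. In 21 of the 35 splits at least 6 lists were called, and 2 other splits called 12, the most of all, so chance cannot be excluded for the count of lists.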

How the results depend on the processing

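Scaling to hybridization controls, the Xist covariate and the joint removal of arrays were chosen only after the results were seen. The 7 genes that rose stayed above 0 under every alternative run. Gpcpd1 stayed past the threshold under 19 of 21 alternatives (adjusted p 0.000568 to 0.304) and Ppp1r2 under 10 of 21 (0.00809 to 0.413). These 21 leave out the averaging of all probe sets of a gene, under which only 1 of the 7 genes stayed past the threshold. The count of 7 genes and 6 probe sets became 11 and 16 with no filter, 14 and 22 with a robust variance (10 and 12 of them higher), and 0 and 0 with no variance trend. It became 114 and 118 scaled to the hybridization controls, which raised the median of all genes by 0.32, and 3 and 1 without both control replicates 7 and 11. There were 10 probe sets with array weights, 10 with the Xist covariate, 2 without both arrays of high Xist, 1 at an adjusted p under 0.01, and 1 gene with all probe sets averaged; the cause was not tested. With each array left out, 0 to 7 genes, 0 to 5 probe sets and 4 to 10 lists passed. Probe sets numbered 0 without hyperthyroid replicate 3 or control replicate 7, and 1, 2 and 3 without hyperthyroid replicate 1, control replicate 8 and hyperthyroid replicate 2. The 6 lists became 0 with an estimated correlation, 0 with fry in 1 direction, 11 (3 higher) without both arrays of high Xist, and 4, of which 1 was higher, scaled to the hybridization controls. Without hyperthyroid replicate 2, 10 lists passed, 4 of them higher. After quantile normalization the fast-fibre median was 0.10, Myh4 0.21, Atp2a1 0.017, Myl1 0.0070 and Tnnt3 0.073. Scaled to the hybridization controls, medians were 0.11 for fast-fibre genes, 0.19 for complex I and 0.072 for complexes II to V, with Myh1 0.11, Myh4 0.20, Slc2a4 0.14 and Fbxo32 0.19. With each array left out, Ucp3 ran from -0.52 to 0.75, Pdk4 from -0.48 to 0.55, Myh1 from -0.36 to 0.033 and Fbxo32 from -0.39 to 0.17. Ucp3 and Pdk4 were lowest without hyperthyroid replicate 1, and turned to -0.092 and -0.34 without control replicate 9 and -0.29 and -0.16 without both arrays of high Xist, where Thrb was -0.029. Fbxo32 turned to 0.17, 0.043 and 0.017 without hyperthyroid replicate 5, control replicate 9 and control replicate 11, and Myh1 turned without hyperthyroid replicate 5. With each array left out, the median intensity differed by -8.81 to -5.04, the values under the pseudocount by 1.05 to 2.03 percentage points, the Gapdh ratio by -0.17 to -0.12, the hybridization controls by -0.42 to -0.27 and the share of the 100 brightest probe sets by -4.61 to -3.62. Exact permutation p-values of these measures ran from 0.0286 to 0.114. Of 1485 values of named genes under alternatives, 1393 kept their direction and side of the threshold, but most of these genes were never past it. Of the others that rose, Syncrip-ps2 and Mcl1 stayed past it under 16 of 21 alternatives, Agpat3 and Pcyox1 under 13 and Mrps18c under 11. Of 138 values of called lists 111 kept both, 23 lost the call and 4 reversed, and of 118 counts and technical measures 78 stayed the same. Transcripts with low signal over background, such as Ucp2 and Dio2, were not tested.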

Other observations

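Past the 7 genes that rose, 5 more had a limma adjusted p between 0.05 and 0.1, and they are named here after their values were seen. Zfp36l1, a protein that promotes the decay of mRNAs, was at 1373 in hyperthyroid and 2940 in control muscle (log2 fold change -1.09 ± 0.18, adjusted p = 0.0676). COX2, a mitochondrially encoded subunit of cytochrome c oxidase, gave -0.71 ± 0.13 (adjusted p = 0.0861), and it ran from -0.78 to -0.10 under the alternatives, with -0.10 after quantile normalization. Gars1, the glycyl-tRNA synthetase, gave 0.83 ± 0.15, Sugt1, a cochaperone, 1.12 ± 0.20, and Ube2d1, a ubiquitin-conjugating enzyme, 1.00 ± 0.18. Their adjusted p-values were 0.0741, 0.0741 and 0.0801, and all 5 genes had groups that did not overlap.

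Connective tissue transcripts varied between arrays of the same group. The mean of the fibroblast and connective tissue markers, as a log2 deviation from the mean of all arrays, was 1.98 on hyperthyroid replicate 5 and 0.70 on control replicate 11, against -0.22, -0.26 and -0.77 on the other hyperthyroid arrays and -0.43, -1.14 and 0.15 on the other controls. The collagen and extracellular matrix genes were highest on the same arrays, at 1.01 and 1.03.

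Xist, transcribed from the inactive X chromosome, had an intensity of 490 on hyperthyroid replicate 1 and 344 on control replicate 11, and at most 49.97 on the other 6 arrays. Each of its probe sets was highest on hyperthyroid replicate 1 and control replicate 11, which were also low in Eif2s3y. These values point to those arrays as the 1 female of each group, although Uty did not follow.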
